A study of Mus musculus with 12 samples.

How the data were processed

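RNA from mouse embryonic fibroblasts was measured on 12 1-colour Agilent arrays, 1 sample to an array, from 100 ng of RNA each per the labels' protocols. The groups were shp53, RASV12, shp53 then RASV12, and RASV12 then shp53, with 3 arrays each that the design text describes as independent biological replicates. Per the file headers, the authors deposited for each spot a processed signal intensity from Agilent Feature Extraction, background-subtracted and spatially detrended within its array and not scaled between arrays. The median pixel intensity of the spot and of its local background was also deposited, with no normalization. The deposited files further hold flags of 0 or 1, another kind of value, for spots well above background, non-uniform, outlying among replicate spots or saturated. The file headers give Feature Extraction version 11.5.1.1 and the submitters' notes version 10.7.3.1, and this difference was left open. The authors also deposited a table of log2 values for 25916 probes. Set against values rebuilt from the arrays, its columns had r from 0.992 to 0.9999 across probes, and they were each array's log2 signal less its 75th percentile, less the median of the 3 shp53 arrays in 99.8% of probes.

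Each array held 44397 spots, 43020 of them not controls, for 39429 probes. 1717 spot values (0.333%) were left out because Feature Extraction marked them as non-uniform or outlying, and 0 were saturated. The processed signal was put on the log2 scale, the array's 75th percentile over spots that are not controls was subtracted, and the spots of a probe were averaged. Probes were kept if well above background on all 3 arrays of at least 1 group, which left 23899. Accessions were paired with gene names through a RefSeq table, used for names only. The headers name an older genome build than that table's, and no coordinates are given. Of the probes, 28330 had 1 gene name and 11099 had none, of which 4855 passed the filter and were not tested. The probe with the highest mean over the arrays stood for a gene with more than 1 kept probe (3824 genes), and 14444 of 21367 named genes were tested.

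All 12 arrays were fitted together in limma 3.58.1 (in R 4.3.3, with version 1.17.8 of data.table) with 1 mean per group, and the 6 pairs of groups were compared with empirical Bayes moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Where no array of 1 group was well above background, a fold is given as a bound. With 3 arrays against 3, an exact two-sided permutation test cannot give a p under 0.1, so the p-values here come from limma's model. The 26 gene lists were CDK inhibitors, DNA replication genes, Hox genes, NRF2 antioxidant genes, RAS-ERK output and feedback genes, X and Y chromosome sex genes, adipocyte markers, amino acid and ER stress genes, antigen presentation genes, cartilage and bone markers, cholesterol synthesis genes, contractile and smooth muscle genes, endothelial markers, epithelial markers, fibroblast extracellular matrix genes, glycolysis and hypoxia genes, interferon-stimulated genes, macrophage and leukocyte markers, matrix proteases and their inhibitors, mesenchymal transition genes, mitosis genes, neural and glial markers, p53 target genes, secreted cytokines and chemokines of senescent cells, skeletal muscle markers and stem cell associated genes. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison.

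The groups, comparisons, lists, tests and the rule for named genes were fixed before the data were examined. The rule took the 10 genes with the highest and the 10 with the lowest log2 fold change in the comparison of the 2 orders, and 5 and 5 in each other comparison. They had to be called, with groups that do not overlap and names that are not clone or locus identifiers. It also took up to 4 members of each described list with the smallest adjusted p, and a fixed set of genes that included Trp53, Hras, Nras, Cdkn1a, Cdkn2a and Mdm2.

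Alternatives fixed in advance were normexp background correction with an offset of 50, quantile scaling, the array median, no filter, a filter on all arrays, the mean of a gene's probes, probes 1 by 1, a trended and robust spread, fits of 2 groups, the slide or replicate as a block, a 2-fold limit, an adjusted p under 0.01, the authors' log2 table and leaving out each array. The mean pixel signal that the normexp plan named was not in the files, and the median pixel signal took its place. Alternatives chosen after the data were seen were averaging the closest arrays, leaving out the arrays that stand apart, leaving out genes of the X and Y chromosomes, fitting the 2 orders alone with the replicate block, and normexp with local backgrounds over 5 times the array's median replaced by that median. The slide held 1 array of each group and had the same number as the replicate, so slide and replicate form 1 block, while position on the slide matched the group and cannot be separated from it. Data for 14444 genes were simulated from the spread of the 2 orders. In them, 50 genes were changed by each of 0.5, 1, 2 and 4 log2 units. Of these limma called 6%, 52%, 76% and 98%, with 2 false calls. The real comparison of the 2 orders called 2282 genes, and each of its groups held 1 pair of close arrays. The simulated shares and false calls therefore need not hold for it.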

Results

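Gene expression was measured in mouse embryonic fibroblasts, primary connective tissue cells grown from mid-gestation embryos, that carried viral vectors for a short hairpin RNA against the p53 mRNA (shp53), for an oncogenic form of RAS (RASV12), or for both. The 12 arrays formed 4 groups of 3. They were shp53 alone, RASV12 alone, shp53 followed by RASV12 (the shp53-first cells) and RASV12 followed by shp53 (the RASV12-first cells). According to the series title, the study set cells transformed after senescence against transformed cells that had not been senescent. Each array held 1 RNA sample in 1 colour, and between 56.6% and 62.4% of its spots were well above background. The number of arrays limits the precision of every value. Log2 fold changes below are given with the standard error from limma, with 3 arrays in each group, and folds written as "at least" are bounds against the lowest signal well above background.

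The first 2 principal components held 48.9% and 22% of the variance and separated the 4 groups. In every group 1 pair of arrays lay far closer than the third. These pairs were replicates 1 and 3 of shp53 and of RASV12, and replicates 2 and 3 of both groups with 2 vectors. The other array of each group is said below to stand apart, and leaving these 4 out together was an alternative chosen after seeing the data. That alternative keeps only the close pairs, so its p-values measure the spread within them and may pass on nearly technical spread. Across genes, r was 0.993 to 0.998 within these pairs and 0.967 to 0.981 in the other pairs of a group. The SD of the difference within the close pairs was 1.16 to 1.65 times that of replicate spots on an array. Each array was kept as a replicate, as the design text describes them, so the p-values measure the spread between these arrays. Totals of called genes and lists are given with their counts when close pairs were averaged, also chosen after seeing the data, and lists with the tests camera and fry.

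**Figure D1:**
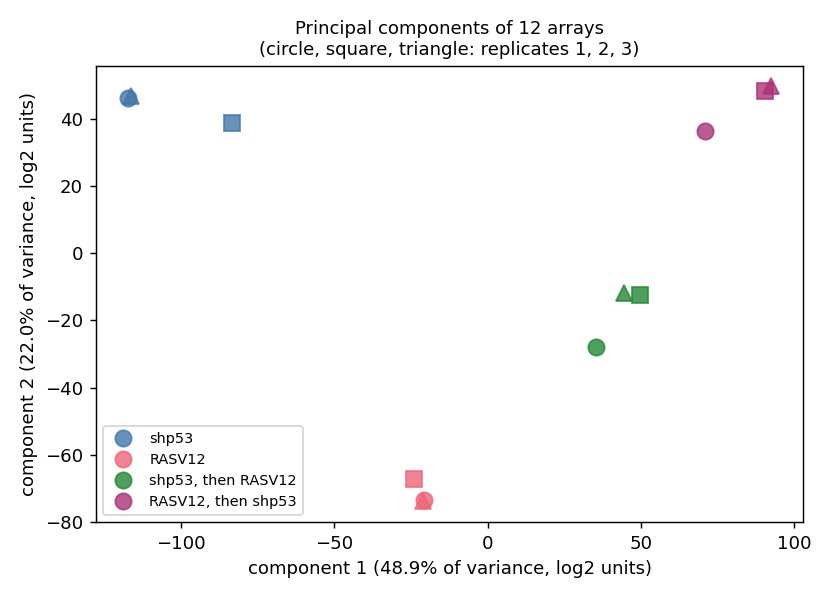
Each point is 1 array on the first 2 principal components of 14444 genes (axes in log2 units, with the percent of variance), coloured by group and shaped by replicate. The 4 groups occupy separate regions, and in each group 1 pair of arrays nearly coincides.

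The target of the hairpin was examined first. Trp53, which encodes p53, had a mean log2 signal, relative to the array's 75th percentile, of -0.56 ± 0.20 (SD, n = 3) in RASV12 cells. It was -3.27 ± 0.25 in shp53 cells, -3.61 ± 0.31 in shp53-first cells and -3.99 ± 0.15 in RASV12-first cells (SD, n = 3 each). Against RASV12 cells, Trp53 was lower by 3.43 log2 units in RASV12-first and by 3.05 in shp53-first cells, a log2 fold change of -3.43 ± 0.20 and -3.05 ± 0.20 (adjusted p = 9.92e-07 and 7.13e-06). Mdm2 and Cdkn1a, both direct p53 targets, had their highest group mean in RASV12 cells, at 5.67 ± 0.18 and 3.66 ± 0.15 (SD, n = 3). The mouse Hras probe, which need not detect the transgene, read 2.61 ± 0.24 in RASV12 cells and 2.08 ± 0.10 in shp53 cells, a log2 difference of 0.53 ± 0.25 that did not pass (adjusted p = 0.155). It passed in a fit of these 2 groups (adjusted p = 0.0425) and without the arrays that stand apart (adjusted p = 0.0013, range over its alternatives 0.0013 to 0.534). Nras also did not pass in that comparison (adjusted p = 0.955), and its 3 probes disagreed, since the brightest was level between these groups while both others read higher in RASV12 cells. With its probes averaged Nras passed as higher (0.63, adjusted p = 0.0243, range over its alternatives 0.0243 to 0.999). Cdkn2a, which encodes the cell-cycle inhibitors p16 and p19Arf, passed in none of the 6 comparisons, with the smallest adjusted p at 0.0925. In RASV12-first against shp53 cells it passed with median centring (adjusted p = 0.00464) and without the arrays that stand apart (adjusted p = 0.0358, range over its alternatives 0.00464 to 0.903).

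**Figure D2:**
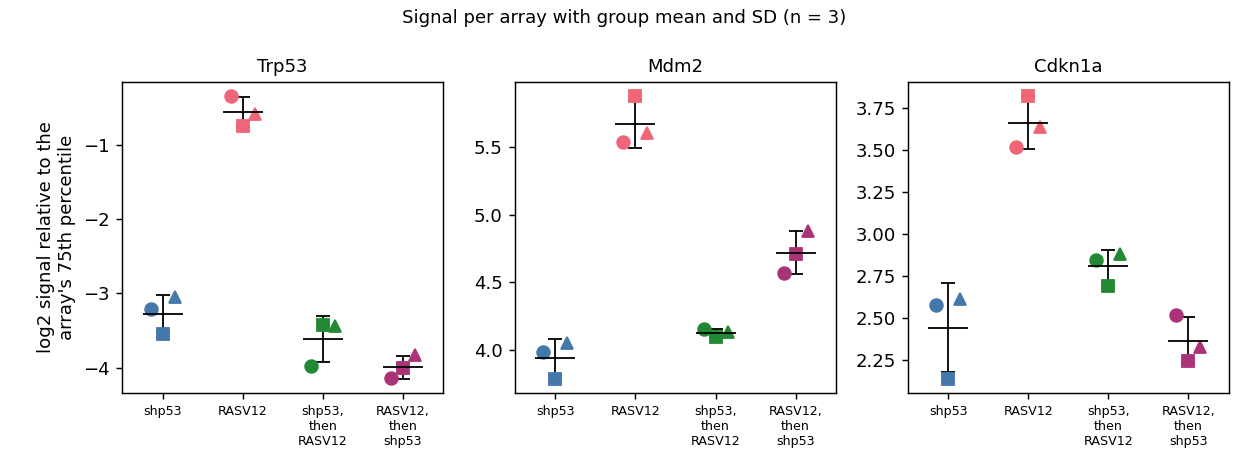
Log2 signal relative to the array's 75th percentile (vertical axis) of Trp53, Mdm2 and Cdkn1a on each array, by group (horizontal axis), with the group mean and SD of 3 arrays. Trp53 is lowest in the 3 groups that carry the hairpin, and Mdm2 and Cdkn1a are highest in the RASV12 group.

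The central comparison asked whether cells with the same pair of vectors differ by the order in which they received them. The labels do not give the litter of the cells, and each order held 1 pair of close arrays. Differences called here can therefore also be differences between cultures. Among the 10 genes with the lowest fold change in RASV12-first against shp53-first cells, Six2 and Tbx1, transcription factors of the developing kidney and pharynx, were at least 266-fold and at least 204-fold lower, Hoxa11 at least 95.1-fold lower, and Bmp4, a secreted morphogen, at least 107-fold lower (adjusted p = 3.76e-07, 1.14e-07, 3.76e-07 and 2.02e-06). The others were Heph (at least 259-fold lower), Ldoc1 (at least 41.3-fold), S100b (at least 45.7-fold), Nmral1 (at least 47.8-fold), Ms4a4d (at least 42.5-fold) and Nrn1, at -7.46 ± 0.24 log2 units. At the other end Pgr, the progesterone receptor, was at least 37.3-fold higher and Apol10b at least 20.4-fold higher in RASV12-first cells. Log2 fold changes of the remaining 8 highest genes were Lce1f 5.25 ± 0.77, Hoxc8 4.71 ± 0.19, Itga2 4.65 ± 0.60, Mrvi1 4.54 ± 0.21, Tfpi2 4.27 ± 0.42, Olfr1466 4.14 ± 0.73, Kprp 4.13 ± 0.49 and Hoxc6 4.13 ± 0.25. Of the shp53-first arrays, 1 measured Lce1f and Olfr1466 well above background, and 2 measured Hoxc8, Itga2, Mrvi1 and Kprp.

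Hox genes, which specify position along the body axis, moved in both directions. Of 33 measured, 10 were higher and 14 lower in RASV12-first cells (11 higher and 15 lower adjusted over the list alone, 7 and 7 with averaged pairs), and a test for a shift one way did not pass (camera adjusted p = 0.629, fry adjusted p = 0.0845, adjusted p = 0.935 with an estimated correlation). Hoxc8 was higher by 4.71 ± 0.19 log2 units, and lower signals were found for Hoxa2 (-4.57 ± 0.21) and Hoxa10 (at least 26-fold lower).

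Secreted cytokines and chemokines of senescent cells were lower in RASV12-first cells, with 9 of 26 members lower and 0 higher (1 higher and 9 lower adjusted over the list alone, 0 and 5 with averaged pairs). The cytokine list had camera adjusted p = 0.00186, fry adjusted p = 0.0199, and adjusted p = 0.935 with an estimated correlation. Cxcl5 and Cxcl1, neutrophil attractants, changed by -4.68 ± 0.42 and -3.92 ± 0.55 log2 units, Igfbp7 by -2.22 ± 0.19 and Ptgs2, the inducible cyclooxygenase, by -1.60 ± 0.22. Contractile genes were higher, 4 of 15 (6 higher and 0 lower adjusted over the list alone, 0 and 0 with averaged pairs). The contractile list had camera adjusted p = 0.00186, fry adjusted p = 0.092, and adjusted p = 0.935 with an estimated correlation, with Actg2 at 3.51 ± 0.54, Cnn1 at 2.03 ± 0.36, Acta2 at 1.73 ± 0.41 and Myl9 at 1.46 ± 0.34. Without RASV12-first replicate 2 or 3, Acta2 (adjusted p = 0.0591 and 0.0646, range over its alternatives 2.99e-05 to 0.478) and Myl9 (adjusted p = 0.0652 and 0.0626, range over its alternatives 2.13e-04 to 0.629) did not pass. The contractile list no longer passed without shp53-first replicate 1 (adjusted p = 0.0525, range over its alternatives 9.79e-05 to 0.935). Of 27 p53 targets, 4 were higher and 4 lower (4 higher and 6 lower adjusted over the list alone, 0 and 1 with averaged pairs). The p53 target list had camera adjusted p = 0.723, fry adjusted p = 0.18, and adjusted p = 0.935 with an estimated correlation, with Perp at -2.89 ± 0.34, Fas at -1.45 ± 0.20 and Mdm2 at 0.59 ± 0.14. Mdm2 did not pass without shp53-first replicate 2 or RASV12-first replicate 3 (adjusted p = 0.0525 and 0.064, range over its alternatives 0.00107 to 0.833). None of 24 mitosis genes passed (0 higher and 0 lower adjusted over the list alone, 0 and 0 with averaged pairs). The mitosis list had camera adjusted p = 0.316, fry adjusted p = 0.774, and adjusted p = 0.935 with an estimated correlation. The median signal of the mitosis genes was 0.19 and 0.78 on replicate 1 of the shp53-first and RASV12-first groups, and 2.10, 2.06, 2.58 and 2.65 on replicates 2 and 3, so that it was higher in RASV12-first cells at each replicate number. These fits did not pair arrays by that number. With the replicate block the mitosis list had 0 higher and 0 lower of 24 (0 higher and 0 lower adjusted over the list alone), camera adjusted p = 0.21, adjusted p = 0.958 with an estimated correlation. In a fit of these 2 groups alone with the block, an alternative chosen after seeing the data, it had 7 higher and 0 lower of 24 (13 higher and 0 lower adjusted over the list alone), camera adjusted p = 4.52e-05, adjusted p = 0.756 with an estimated correlation. Interferon-stimulated genes had 0 higher and 1 lower of 26 (0 higher and 1 lower adjusted over the list alone, 0 and 0 with averaged pairs), camera adjusted p = 0.238, fry adjusted p = 0.654, adjusted p = 0.935 with an estimated correlation. With the replicate block they had 0 higher and 1 lower of 26 (0 higher and 1 lower adjusted over the list alone), camera adjusted p = 0.21, adjusted p = 0.958 with an estimated correlation, and in the paired fit of 2 groups 0 higher and 11 lower of 26 (0 higher and 16 lower adjusted over the list alone), camera adjusted p = 9.55e-06, adjusted p = 0.756 with an estimated correlation. Trp53 itself did not pass (-0.38 ± 0.20, adjusted p = 0.235), but it passed as lower in RASV12-first cells without the arrays that stand apart (adjusted p = 0.0139, range over its alternatives 0.0139 to 0.751). Of the 2 Cdkn1a probes the brighter gave -0.44 ± 0.16 (adjusted p = 0.0864) while the dimmer read lower still in RASV12-first cells. Cdkn1a passed with its probes averaged (adjusted p = 0.0111) and without the arrays that stand apart (adjusted p = 0.00552, range over its alternatives 0.00552 to 0.706).

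In all, 2282 of 14444 genes passed an adjusted p of 0.05 in limma, 1059 higher and 1223 lower, and 1297 of them differed at least 2-fold. The share higher was 46.4%, and it was 68.5% when arrays were centred on their median, which put the median of all genes at 0.25 log2 units. It was 22.2% with averaged pairs, 21.5% with normexp and 30.7% of genes at least 2-fold apart, with a range over all alternatives of 21.5% to 68.5%. With the closest pair of arrays in each group averaged, an alternative chosen after seeing the data, 424 genes passed, and the count was 65 with normexp background correction and 1284 when 77 extreme local backgrounds were first replaced. Fitting these 2 groups alone gave 1381 genes, and 2498 with the replicate block added after seeing the data, while leaving out RASV12-first replicate 3 gave 1485. Without the arrays that stand apart, where only the closest pairs are left, 6937 genes passed. With the replicate number, which is also the slide, as a block the count was 2267.

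**Figure D3:**
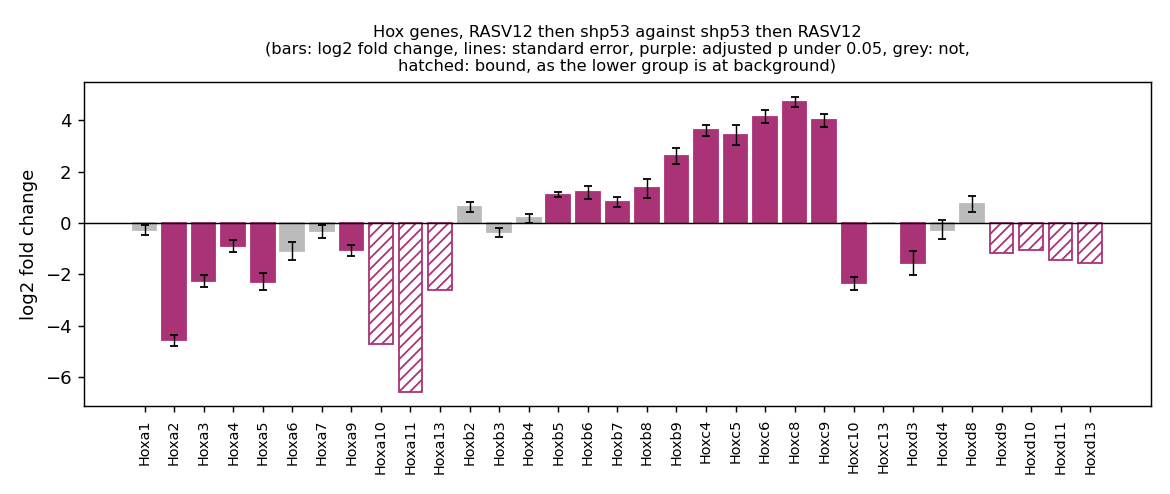
Log2 fold change of 33 Hox genes (horizontal axis) between RASV12-first and shp53-first cells (vertical axis), with the standard error from 3 arrays per group. Purple bars passed an adjusted p of 0.05, with 10 higher and 14 lower. Hatched bars are bounds for 7 genes that no RASV12-first array measured well above background, and Hoxc13, named after its values were seen, has no bar because it was above background in neither group.

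RASV12 cells were set against shp53 cells to compare the first vectors alone. No group without a vector was measured. Genes said to rise or fall here are higher or lower in RASV12 than in shp53 cells, and which group moved cannot be told. S100a8, a calcium-binding protein of inflamed tissue, was at least 616-fold higher in RASV12 cells (adjusted p = 1.11e-05). The other 4 of the 5 genes with the highest fold change were Prl2c5, Prl3d2 and Prl3d1, with log2 fold changes of 10.45 ± 0.63, 10.35 ± 0.85 and 9.68 ± 0.53, and Prl8a9, at least 111-fold higher. Close paralogs of these genes can share probe signal. The largest decreases were Cx3cr1, a receptor of macrophages (at least 157-fold lower), and the matrix-associated genes Abi3bp -8.16 ± 0.87, Aspn -8.13 ± 0.96 and Fndc1 -7.81 ± 0.90, with Scg2 at -7.83 ± 1.50. Each of Abi3bp, Aspn, Fndc1 and Scg2 was well above background on 1 RASV12 array, and Prl3d2 on 1 shp53 array.

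p53 targets rose in RASV12 cells, 15 of 27 higher and 1 lower (15 higher and 1 lower adjusted over the list alone, 5 and 1 with averaged pairs). The p53 target list had camera adjusted p = 7.29e-05, fry adjusted p = 2.16e-05, and adjusted p = 0.079 with an estimated correlation, with Perp 4.32 ± 0.34, Mdm2 1.73 ± 0.14 and Ccng1 1.49 ± 0.18, whereas Sesn1 changed by -1.61 ± 0.17. RAS-ERK output and feedback genes rose, 17 of 25 higher and 2 lower (18 higher and 2 lower adjusted over the list alone, 12 and 1 with averaged pairs). The RAS-ERK list had camera adjusted p = 3.90e-07, fry adjusted p = 9.82e-06, and adjusted p = 0.079 with an estimated correlation, with Lif 4.46 ± 0.26, Fosl1 3.21 ± 0.22, Ereg 3.62 ± 0.33 and Etv4 1.86 ± 0.19. Secreted cytokines and chemokines rose in 14 of 26 and fell in 1 (14 higher and 1 lower adjusted over the list alone, 11 and 0 with averaged pairs). The cytokine list had camera adjusted p = 1.46e-05, fry adjusted p = 2.60e-04, and adjusted p = 0.371 with an estimated correlation. The list's median was -0.24, 1.77 and -0.53 on RASV12 replicates 1, 2 and 3 and 0.15, -1.37 and 0.15 on those of shp53, and without the arrays that stand apart the list did not pass (adjusted p = 0.192, range over its alternatives 1.37e-07 to 0.371). Il1a, an upstream inflammatory cytokine, was at least 38.4-fold higher, Cxcl3 changed by 6.09 ± 0.38 and Ptgs2 by 3.12 ± 0.22. Glycolysis and hypoxia genes rose in 13 of 22 (14 higher and 0 lower adjusted over the list alone, 0 and 0 with averaged pairs). The glycolysis list had camera adjusted p = 2.66e-04, fry adjusted p = 0.046, and adjusted p = 0.566 with an estimated correlation, with Vegfa at 1.20 ± 0.26 and Car9 at 1.49 ± 0.33. NRF2 antioxidant genes were higher in 7 of 13 (8 higher and 1 lower adjusted over the list alone, 2 and 0 with averaged pairs). The NRF2 list had camera adjusted p = 0.0047, fry adjusted p = 0.00442, and adjusted p = 0.488 with an estimated correlation, with Srxn1 at 1.44 ± 0.20 and Hmox1 at 1.85 ± 0.38. Its median was 0.89, 2.49 and 0.98 on the RASV12 and 1.05, 0.77 and 1.11 on the shp53 arrays, so that only RASV12 replicate 2 lay above the shp53 arrays, and the list did not pass without the arrays that stand apart (adjusted p = 0.165, range over its alternatives 7.52e-04 to 0.488).

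Fibroblast matrix genes fell, 21 of 26 lower and 0 higher (0 higher and 21 lower adjusted over the list alone, 0 and 7 with averaged pairs). The matrix list had camera adjusted p = 2.82e-10, fry adjusted p = 3.68e-04, and adjusted p = 0.371 with an estimated correlation, with Fbn1 -2.25 ± 0.19, Eln -5.13 ± 0.43, Fbln5 -2.83 ± 0.24 and Ogn -6.18 ± 0.54. Cholesterol synthesis genes fell in 9 of 20 and rose in 1 (1 higher and 10 lower adjusted over the list alone, 0 and 2 with averaged pairs). The cholesterol list had camera adjusted p = 1.06e-04, fry adjusted p = 0.046, and adjusted p = 0.561 with an estimated correlation, with Dhcr7 at -1.26 ± 0.16 and Hmgcs1 at -1.60 ± 0.26. Amino acid and ER stress genes fell in 6 of 18 (0 higher and 8 lower adjusted over the list alone, 0 and 1 with averaged pairs). The ER stress list had camera adjusted p = 0.00349, fry adjusted p = 0.0278, and adjusted p = 0.52 with an estimated correlation, with Herpud1 at -1.49 ± 0.21 and Asns at -1.32 ± 0.29. It did not pass with normexp background correction (adjusted p = 0.236, range over its alternatives 1.30e-04 to 0.52). The mitosis list passed as lower (camera adjusted p = 0.00306, fry adjusted p = 0.258, adjusted p = 0.753 with an estimated correlation) with 1 of 24 members called, Cenpa at -1.44 ± 0.46, and none adjusted over the list alone or with averaged pairs. Cenpa did not pass without any 1 of the 6 arrays, with adjusted p = 0.0844 to 0.105. Macrophage and leukocyte markers fell in 12 of 13 (0 higher and 12 lower adjusted over the list alone, 0 and 1 with averaged pairs). The macrophage list had camera adjusted p = 1.68e-06, fry adjusted p = 0.00791, and adjusted p = 0.464 with an estimated correlation, with C1qa at -7.79 ± 1.25. The markers' median signal was 2.89 and 2.92 on shp53 replicates 1 and 3 and -1.42 on shp53 replicate 2, against -2.88, -2.03 and -2.86 on the RASV12 arrays.

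In all, 3916 of 14444 genes passed an adjusted p of 0.05 in limma, 2068 higher and 1848 lower, and 2262 of them differed at least 2-fold, 1072 higher and 1190 lower. With the closest pair of arrays in each group averaged, an alternative chosen after seeing the data, 1031 genes passed, and the count was 434 with normexp background correction and 3000 when 77 extreme local backgrounds were first replaced.

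**Figure D4:**
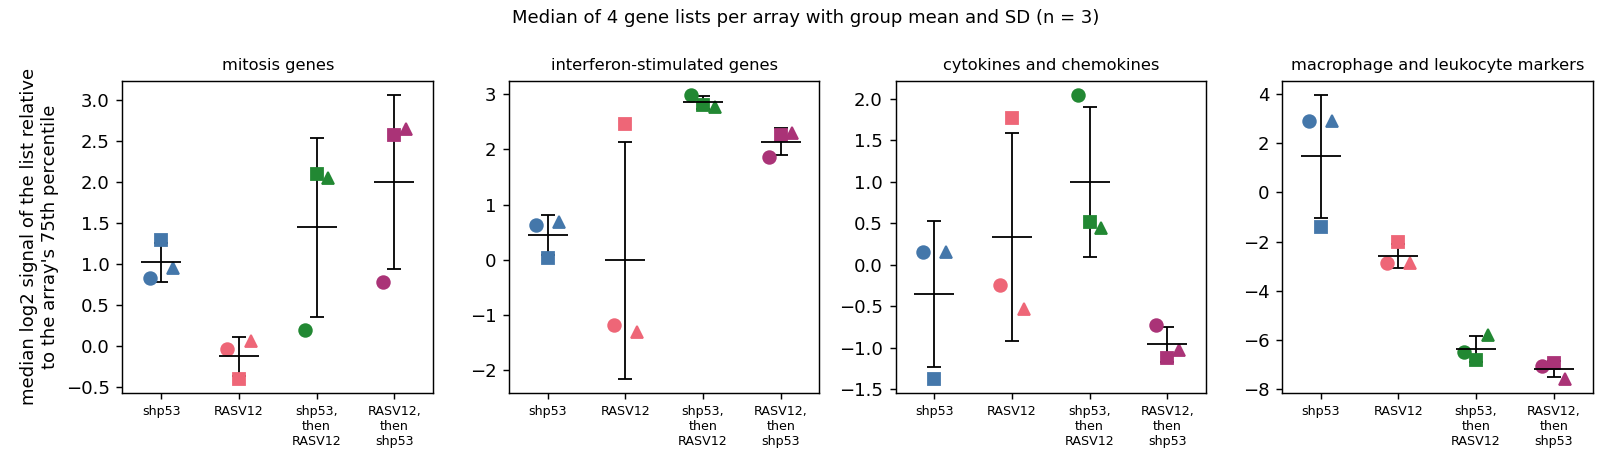
Median log2 signal of 4 gene lists relative to the array's 75th percentile (vertical axes) on each array, by group (horizontal axes), with the group mean and SD of 3 arrays. Macrophage markers are highest on shp53 replicates 1 and 3, interferon-stimulated genes are lowest on RASV12 replicates 1 and 3, while RASV12 replicate 2 lies above the shp53 arrays and with the arrays that carry 2 vectors, and mitosis genes are highest on replicates 2 and 3 of both groups with 2 vectors.

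The genes by which RASV12 and shp53 cells differ were then followed into the comparison of the 2 orders, which shares no array with it. Of 1025 genes called in both, 463 changed in 1 direction and 562 in opposite directions. 208 genes were higher in both and 255 lower in both, where independent lists would share 152 and 156. A further 208 were higher in RASV12-first and lower in RASV12 cells, and 354 the reverse, against 135 and 175. All arrays were fitted together, so both calls of a gene used the same estimate of its spread. Genes with a small spread can therefore be called in both comparisons more often than independent lists allow. The excess over the counts for independent lists thus cannot show that the comparisons are related. Across genes, which are not independent replicates, r of the fold changes was -0.045, and 4 of 10 splits of the 6 arrays gave an r at least that far from 0. As sets, the genes higher in RASV12 cells had no shift with the order of the vectors that passed (camera p = 0.0683, p = 0.152 with an estimated correlation). Those lower in RASV12 cells had none either (camera p = 0.566, p = 0.829 with an estimated correlation). The cells with 1 vector differed from both orders in sex-linked signals, described below. Whether effects of a first vector last therefore cannot be told from these results. Averaging the close pairs left 43 genes with 1 direction in both, normexp 3, its version with replaced backgrounds 224 and fits of 2 groups at a time 306, and without RASV12-first replicate 2 or 3 there were 301 and 297. The count rose without the arrays that stand apart, where only the closest pairs are left.

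The shp53-first cells were then compared with shp53 cells. Sex-linked signals also differed between all cells with 1 vector and all cells with 2. Changes in comparisons of 2 vectors with 1 therefore cannot be put down to the added vector alone. Eif2s3y, a Y-linked gene, was at least 108-fold higher and Xist, the X-inactivation transcript, at least 39.1-fold lower in the cells with 2 vectors (adjusted p = 5.62e-10 and 9.25e-08). RAS-ERK output genes were higher, 15 of 25 with 3 lower (15 higher and 3 lower adjusted over the list alone, 11 and 0 with averaged pairs). The RAS-ERK list had camera adjusted p = 4.70e-05, fry adjusted p = 3.37e-05, and adjusted p = 0.372 with an estimated correlation, with Fosl1 3.25 ± 0.22, Lif 3.83 ± 0.26, Etv4 1.75 ± 0.19 and Dusp6 2.15 ± 0.27. Secreted cytokines and chemokines were higher in 13 of 26 and lower in 3 (14 higher and 3 lower adjusted over the list alone, 9 and 2 with averaged pairs). The cytokine list had camera adjusted p = 0.00419, fry adjusted p = 0.00147, and adjusted p = 0.563 with an estimated correlation, with Csf2 at least 79.7-fold higher. The call ended without shp53 replicate 2 (adjusted p = 0.0604) and without the arrays that stand apart (adjusted p = 0.176, range over its alternatives 2.69e-04 to 0.563). Antigen presentation genes were higher in 10 of 15 (10 higher and 0 lower adjusted over the list alone, 7 and 0 with averaged pairs). The antigen presentation list had camera adjusted p = 3.80e-04, fry adjusted p = 0.00324, and adjusted p = 0.563 with an estimated correlation, with Tap1 2.37 ± 0.26, Nlrc5 4.08 ± 0.49 and H2-D1 2.74 ± 0.39. Interferon-stimulated genes were higher in 11 of 26 (14 higher and 0 lower adjusted over the list alone, 2 and 0 with averaged pairs). The interferon list had camera adjusted p = 8.70e-05, fry adjusted p = 0.0673, and adjusted p = 0.777 with an estimated correlation, with Ifit2 at 1.84 ± 0.20. DNA replication genes were higher in 8 of 28 (8 higher and 0 lower adjusted over the list alone, 1 and 0 with averaged pairs). The replication list had camera adjusted p = 2.12e-04, fry adjusted p = 0.0806, and adjusted p = 0.777 with an estimated correlation, with Cdt1 at 1.64 ± 0.25. Its median was 0.84 on shp53-first replicate 1, within the shp53 arrays (0.82, 0.88 and 0.79), and 2.30 and 2.31 on replicates 2 and 3. Cholesterol synthesis genes were lower in 18 of 20 (0 higher and 19 lower adjusted over the list alone, 0 and 8 with averaged pairs). The cholesterol list had camera adjusted p = 5.79e-07, fry adjusted p = 0.00354, and adjusted p = 0.563 with an estimated correlation, with Hmgcs1 -2.44 ± 0.26, Sqle -2.78 ± 0.38 and Msmo1 -2.16 ± 0.30. Matrix genes were lower in 20 of 26 (0 higher and 21 lower adjusted over the list alone, 0 and 11 with averaged pairs). The matrix list had camera adjusted p = 7.33e-08, fry adjusted p = 1.64e-04, and adjusted p = 0.563 with an estimated correlation, with Fbln5 -3.55 ± 0.24, Ogn -7.57 ± 0.54 and Mfap5 -4.99 ± 0.37. Contractile genes were lower in 11 of 15 with 1 higher (1 higher and 12 lower adjusted over the list alone, 0 and 7 with averaged pairs). The contractile list had camera adjusted p = 3.70e-05, fry adjusted p = 0.00121, and adjusted p = 0.563 with an estimated correlation, with Actg2 at -6.94 ± 0.54. Amino acid and ER stress genes were lower in 7 of 18 (0 higher and 7 lower adjusted over the list alone, 0 and 0 with averaged pairs). The ER stress list had camera adjusted p = 0.0173, fry adjusted p = 0.0334, and adjusted p = 0.777 with an estimated correlation, and its median was 2.65, 1.40 and 1.34 on the shp53-first and 3.05, 2.87 and 3.03 on the shp53 arrays. The call was lost without shp53-first replicate 2 or 3 (adjusted p = 0.0593 and 0.0654), with normexp (adjusted p = 0.0616) and with averaged pairs (adjusted p = 0.0924, range over its alternatives 1.18e-04 to 0.777). Macrophage markers were lower in 12 of 13 (0 higher and 12 lower adjusted over the list alone, 0 and 8 with averaged pairs). The macrophage list had camera adjusted p = 6.24e-07, fry adjusted p = 0.00121, and adjusted p = 0.563 with an estimated correlation, with Ctss at least 466-fold and Tyrobp at least 301-fold lower. The markers' median was -6.48, -6.84 and -5.80 on the shp53-first arrays, and 2.89, -1.42 and 2.92 on shp53 replicates 1, 2 and 3.

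Among single genes, S100a8 (at least 221-fold) and Rasgrf1 (at least 119-fold) were higher in shp53-first cells, as were Prl2c5 (9.21 ± 0.63) and Lcn2 (8.20 ± 0.63). Ms4a7, C1qc, Col10a1 and Ecrg4 were at least 598-fold, at least 412-fold, at least 459.8-fold and at least 289-fold lower. Whether these folds follow the macrophage markers, which differed among the shp53 arrays, was not tested. In all, 5431 of 14444 genes passed an adjusted p of 0.05 in limma, 2496 higher and 2935 lower, and 3009 of them differed at least 2-fold. With the closest pair of arrays in each group averaged, an alternative chosen after seeing the data, 1702 genes passed, and the count was 383 with normexp background correction and 4384 when 77 extreme local backgrounds were first replaced.

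RASV12-first cells were compared with RASV12 cells, which carried no hairpin and differed in the sex-linked signals too. Eif2s3y, a Y-linked gene, was at least 138-fold higher and Xist, the X-inactivation transcript, at least 31.5-fold lower in the cells with 2 vectors (adjusted p = 4.07e-10 and 8.66e-08). p53 targets were lower, 17 of 27 with 1 higher (2 higher and 18 lower adjusted over the list alone, 0 and 10 with averaged pairs). The p53 target list had camera adjusted p = 1.26e-05, fry adjusted p = 7.51e-07, and adjusted p = 0.0894 with an estimated correlation, with Perp -7.35 ± 0.34, Ddit4l -3.32 ± 0.24, Fas -2.11 ± 0.20 and Ephx1 -1.88 ± 0.21. Secreted cytokines and chemokines were lower in 15 of 26 and higher in 3 (3 higher and 16 lower adjusted over the list alone, 1 and 9 with averaged pairs). The cytokine list had camera adjusted p = 7.83e-04, fry adjusted p = 1.31e-04, and adjusted p = 0.629 with an estimated correlation, with Cxcl3 at least 67.2-fold and Il1a at least 33.6-fold lower and Cxcl5 at -8.47 ± 0.42. Ccl5 and Cxcl10, chemokines induced by interferon, went the other way, at 7.30 ± 1.19 and 5.68 ± 1.27. Mitosis genes were higher in 18 of 24 (20 higher and 0 lower adjusted over the list alone, 1 and 0 with averaged pairs). The mitosis list had camera adjusted p = 2.61e-06, fry adjusted p = 0.0359, and adjusted p = 0.739 with an estimated correlation, with Bub1b 2.69 ± 0.43, Cenpa 2.08 ± 0.46 and Tpx2 1.95 ± 0.47. Its median was 0.78, 2.58 and 2.65 on the RASV12-first and -0.04, -0.39 and 0.06 on the RASV12 arrays. DNA replication genes were higher in 17 of 28 (19 higher and 0 lower adjusted over the list alone, 3 and 0 with averaged pairs). The replication list had camera adjusted p = 2.61e-06, fry adjusted p = 0.0244, and adjusted p = 0.739 with an estimated correlation, with E2f2 3.70 ± 0.28, Cdt1 2.30 ± 0.25 and Prim1 2.85 ± 0.40. The median of the replication list was 1.15, 2.17 and 2.36 and 0.51, 0.26 and 0.61 on these arrays. Interferon-stimulated genes were higher in 13 of 26 (20 higher and 1 lower adjusted over the list alone, 0 and 0 with averaged pairs). The interferon list had camera adjusted p = 2.49e-04, fry adjusted p = 0.0966, and adjusted p = 0.739 with an estimated correlation, with Irf7 at 3.57 ± 0.85. Antigen presentation genes were higher in 8 of 15 with 1 lower (10 higher and 1 lower adjusted over the list alone, 2 and 0 with averaged pairs). The antigen presentation list had camera adjusted p = 7.46e-04, fry adjusted p = 0.00797, and adjusted p = 0.629 with an estimated correlation, with Psmb9 at 5.02 ± 0.62. The median of the interferon list was -1.17 and -1.31 on RASV12 replicates 1 and 3 and 2.45 on RASV12 replicate 2, which lay with the RASV12-first arrays (1.87, 2.26 and 2.30). Cholesterol synthesis genes were lower in 10 of 20 and higher in 1 (1 higher and 11 lower adjusted over the list alone, 0 and 1 with averaged pairs). The cholesterol list had camera adjusted p = 0.00858, fry adjusted p = 0.044, and adjusted p = 0.79 with an estimated correlation, and its median was -0.33, -0.59 and -0.60 on the RASV12-first and 0.38, -0.42 and 0.50 on the RASV12 arrays. Macrophage markers were lower in 5 of 13 (0 higher and 5 lower adjusted over the list alone, 0 and 1 with averaged pairs). The macrophage list had camera adjusted p = 0.0415, fry adjusted p = 0.0762, and adjusted p = 0.809 with an estimated correlation. The call ended without RASV12 replicate 2 (adjusted p = 0.105), without RASV12-first replicate 1 or 3 (adjusted p = 0.0988 and 0.0574). It also ended with a gene's probes averaged (adjusted p = 0.0513) and with genes above background on all arrays (adjusted p = 0.507, range over its alternatives 1.89e-05 to 0.809), and with normexp after extreme backgrounds were replaced (adjusted p = 0.415), and the list turned in direction with normexp as planned.

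The lowest single genes in RASV12-first cells were Ppbp (at least 412-fold lower), Anxa8 (at least 339-fold), S100b (at least 167-fold), Hp, which encodes haptoglobin (at least 573-fold), and Prl3d2 (-9.70 ± 0.85). Besides Eif2s3y, Ccl5 and Cxcl10, the highest were Ddx3y, also Y-linked (at least 41.9-fold higher), and Pgr (at least 40.9-fold). Mdm2 fell by 0.96 and Cdkn1a by 1.29 log2 units, with fold changes of -0.96 ± 0.14 and -1.29 ± 0.16. The mouse Hras probe was also lower, at -1.31 ± 0.25 (adjusted p = 0.00279). In all, 5610 of 14444 genes passed an adjusted p of 0.05 in limma, 2479 higher and 3131 lower, and 2950 of them differed at least 2-fold. The share higher was 44.2%, and 63.6% with arrays centred on their median, which put the median of all genes at 0.19. It was 33% with averaged pairs, 36.2% with normexp and 37.4% of genes at least 2-fold apart, with a range over all alternatives of 33% to 63.6%. With the closest pair of arrays in each group averaged, an alternative chosen after seeing the data, 1489 genes passed, and the count was 821 with normexp background correction and 4221 when 77 extreme local backgrounds were first replaced.

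RASV12-first cells were also set against shp53 cells. Eif2s3y, a Y-linked gene, was at least 156-fold higher and Xist, the X-inactivation transcript, at least 36.9-fold lower in the cells with 2 vectors (adjusted p = 3.06e-10 and 5.58e-08). All 20 measured cholesterol synthesis genes were lower (0 higher and 20 lower adjusted over the list alone, 0 and 11 with averaged pairs). The cholesterol list had camera adjusted p = 1.11e-06, fry adjusted p = 0.00196, and adjusted p = 0.635 with an estimated correlation, with Mvk -2.40 ± 0.29, Hmgcs1 -2.14 ± 0.26, Insig1 -3.13 ± 0.38 and Sqle -3.12 ± 0.38, and they stayed lower as a list under the quantile and median scalings. RAS-ERK output genes were higher in 16 of 25 and lower in 4 (16 higher and 4 lower adjusted over the list alone, 10 and 0 with averaged pairs). The RAS-ERK list had camera adjusted p = 4.08e-04, fry adjusted p = 1.65e-05, and adjusted p = 0.599 with an estimated correlation, with Fosl1 3.33 ± 0.22, Etv4 2.76 ± 0.19, Lif 3.64 ± 0.26 and Dusp6 2.72 ± 0.27. Antigen presentation genes were higher in 11 of 15 and lower in 2 (11 higher and 2 lower adjusted over the list alone, 7 and 0 with averaged pairs). The antigen presentation list had camera adjusted p = 0.00288, fry adjusted p = 0.00241, and adjusted p = 0.635 with an estimated correlation, with Nlrc5 at 4.87 ± 0.49. DNA replication genes were higher in 13 of 28 (14 higher and 0 lower adjusted over the list alone, 2 and 0 with averaged pairs). The replication list had camera adjusted p = 4.08e-04, fry adjusted p = 0.0532, and adjusted p = 0.739 with an estimated correlation, with Cdt1 at 2.26 ± 0.25, and its median was 1.15, 2.17 and 2.36 on the RASV12-first and 0.82, 0.88 and 0.79 on the shp53 arrays. Matrix genes were lower in 15 of 26 (1 higher and 16 lower adjusted over the list alone, 0 and 12 with averaged pairs). The matrix list had camera adjusted p = 5.87e-06, fry adjusted p = 3.19e-04, and adjusted p = 0.635 with an estimated correlation, with Lox at -4.79 ± 0.23 and Mfap5 at -7.07 ± 0.37. Amino acid and ER stress genes were lower in 6 of 18 (0 higher and 6 lower adjusted over the list alone, 0 and 2 with averaged pairs). The ER stress list had camera adjusted p = 0.0218, fry adjusted p = 0.0151, and adjusted p = 0.635 with an estimated correlation, with Trib3 at -3.43 ± 0.63. Macrophage markers were lower in 12 of 13 (0 higher and 12 lower adjusted over the list alone, 0 and 9 with averaged pairs). The macrophage list had camera adjusted p = 3.79e-06, fry adjusted p = 0.00101, and adjusted p = 0.635 with an estimated correlation, with Ctss at least 439.6-fold lower. The markers' median was -7.07, -6.95 and -7.57 on the RASV12-first arrays, and 2.89, -1.42 and 2.92 on shp53 replicates 1, 2 and 3. Contractile genes were lower in 7 of 15 and higher in 1 (1 higher and 7 lower adjusted over the list alone, 1 and 4 with averaged pairs). The contractile list had camera adjusted p = 0.0295, fry adjusted p = 0.0221, and adjusted p = 0.739 with an estimated correlation. The call ended without RASV12-first replicate 1 (adjusted p = 0.152), among genes above background on all arrays (adjusted p = 0.0854) and without the arrays that stand apart (adjusted p = 0.0747, range over its alternatives 0.0035 to 0.739). The mitosis list passed as higher (camera adjusted p = 0.0295, fry adjusted p = 0.233, adjusted p = 0.835 with an estimated correlation) with 1 of 24 members called (1 higher and 0 lower adjusted over the list alone, 0 and 0 with averaged pairs). Its median on RASV12-first replicate 1, 0.78, lay below the shp53 arrays (0.83, 1.29 and 0.95), and it was not called with averaged pairs (adjusted p = 0.138). The interferon list passed too (camera adjusted p = 0.037, fry adjusted p = 0.216, adjusted p = 0.835 with an estimated correlation), with 5 of 26 higher and 1 lower (5 higher and 1 lower adjusted over the list alone, 1 and 0 with averaged pairs). Both of these calls ended with quantile scaling (adjusted p = 0.0514 and 0.0681), with median centring (adjusted p = 0.176 and 0.176) and among genes above background on all arrays (adjusted p = 0.0587 and 0.0587; range over its alternatives 4.09e-09 to 0.835 and 1.41e-05 to 0.835). They also ended without RASV12-first replicate 2 (adjusted p = 0.116 and 0.0572) or 3 (adjusted p = 0.129 and 0.0666), and that of the interferon list without shp53 replicate 2 (adjusted p = 0.209) or RASV12-first replicate 1 (adjusted p = 0.0571). Cytokines and chemokines split, 9 higher and 10 lower of 26 (9 higher and 10 lower adjusted over the list alone, 8 and 3 with averaged pairs). The cytokine list had camera adjusted p = 0.594, fry adjusted p = 0.441, and adjusted p = 0.872 with an estimated correlation, with Csf2 at least 27.8-fold higher and Igfbp7 at -3.70 ± 0.19.

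Cxcl14, a constitutive tissue chemokine, was at least 1489.6-fold lower in RASV12-first than in shp53 cells, followed by Lyz1 (at least 596-fold), Ms4a7 (at least 565-fold), Ccn5 (at least 557-fold) and Col10a1 (at least 434-fold). Whether any of these folds follow the macrophage markers, which differed among the shp53 arrays, was not tested. Rasgrf1, Sprr2e and Rspo4 were at least 97.5-fold, at least 56.1-fold and at least 51-fold higher, and H2-Q5 changed by 7.61 ± 0.33, where paralogs of Sprr2e and H2-Q5 can share probe signal. In all, 6577 of 14444 genes passed an adjusted p of 0.05 in limma, 3138 higher and 3439 lower, and 3612 of them differed at least 2-fold. The share higher was 47.7%, and 68.6% with arrays centred on their median, which put the median of all genes at 0.36. It was 39.5% with averaged pairs, 27.5% with normexp and 38.6% of genes at least 2-fold apart, with a range over all alternatives of 27.5% to 68.6%. With the closest pair of arrays in each group averaged, an alternative chosen after seeing the data, 2481 genes passed, and the count was 349 with normexp background correction and 5289 when 77 extreme local backgrounds were first replaced.

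The last comparison, shp53-first against RASV12 cells, had the 1 list that passed under both settings of camera. p53 targets were lower in 16 of 27 and higher in 0 (1 higher and 17 lower adjusted over the list alone, 0 and 5 with averaged pairs). The p53 target list had camera adjusted p = 2.01e-07, fry adjusted p = 2.11e-06, and adjusted p = 0.0373 with an estimated correlation, with Perp -4.46 ± 0.34, Mdm2 -1.55 ± 0.14, Ddit4l -2.11 ± 0.24 and Ephx1 -1.78 ± 0.21. Eif2s3y, a Y-linked gene, was at least 95.8-fold higher and Xist, the X-inactivation transcript, at least 33.4-fold lower in the cells with 2 vectors (adjusted p = 7.61e-10 and 3.83e-07). Interferon-stimulated genes were higher in 20 of 26 (24 higher and 0 lower adjusted over the list alone, 0 and 0 with averaged pairs). The interferon list had camera adjusted p = 1.20e-09, fry adjusted p = 0.0284, and adjusted p = 0.534 with an estimated correlation, with Irf7 3.98 ± 0.85, Oasl2 3.84 ± 0.92 and Ifit3 4.39 ± 1.05. Without RASV12 replicate 1 or 3, Oasl2 (adjusted p = 0.0543 and 0.0558, range over its alternatives 1.28e-06 to 0.234) and Ifit3 (adjusted p = 0.0552 and 0.0562, range over its alternatives 2.33e-07 to 0.239) did not pass. The list's median lay at 2.98, 2.80 and 2.77 on the shp53-first arrays and at 2.45 on RASV12 replicate 2. Antigen presentation genes were higher in 8 of 15 (9 higher and 0 lower adjusted over the list alone, 1 and 0 with averaged pairs). The antigen presentation list had camera adjusted p = 2.72e-05, fry adjusted p = 0.0129, and adjusted p = 0.534 with an estimated correlation, with Psmb9 at 3.75 ± 0.62. DNA replication genes were higher in 12 of 28 (19 higher and 0 lower adjusted over the list alone, 1 and 0 with averaged pairs). The replication list had camera adjusted p = 3.79e-08, fry adjusted p = 0.037, and adjusted p = 0.601 with an estimated correlation, with E2f2 at 2.77 ± 0.28, and its median was 0.84, 2.30 and 2.31 on the shp53-first and 0.51, 0.26 and 0.61 on the RASV12 arrays. Mitosis genes were higher in 5 of 24 (5 higher and 0 lower adjusted over the list alone, 0 and 0 with averaged pairs). The mitosis list had camera adjusted p = 3.07e-06, fry adjusted p = 0.08, and adjusted p = 0.601 with an estimated correlation, with Bub1b at 1.80 ± 0.43. The list's median was 0.19 on shp53-first replicate 1, near the RASV12 arrays (-0.04, -0.39 and 0.06), and 2.10 and 2.06 on replicates 2 and 3. Bub1b did not pass without shp53-first replicate 2 (adjusted p = 0.0528, range over its alternatives 6.84e-06 to 0.198). Contractile genes were lower in 10 of 15 (0 higher and 11 lower adjusted over the list alone, 0 and 2 with averaged pairs). The contractile list had camera adjusted p = 2.54e-05, fry adjusted p = 0.0076, and adjusted p = 0.534 with an estimated correlation, with Actg2 at -3.97 ± 0.54. Glycolysis and hypoxia genes were lower in 5 of 22 (0 higher and 5 lower adjusted over the list alone, 0 and 1 with averaged pairs). The glycolysis list had camera adjusted p = 0.00664, fry adjusted p = 0.08, and adjusted p = 0.601 with an estimated correlation, with Car9 at -3.19 ± 0.33. Its median was 2.38 on shp53-first replicate 1, above the RASV12 arrays (2.15, 2.07 and 2.11), and 0.71 and 0.71 on replicates 2 and 3. Cholesterol synthesis genes were lower in 5 of 20 (0 higher and 6 lower adjusted over the list alone, 0 and 0 with averaged pairs). The cholesterol list had camera adjusted p = 0.00664, fry adjusted p = 0.08, and adjusted p = 0.601 with an estimated correlation, with Mvk at -1.45 ± 0.29. The call ended without shp53-first replicate 1 (adjusted p = 0.136, range over its alternatives 1.26e-04 to 0.601), and the list's median was -1.02, 0.27 and 0.36 on the shp53-first and 0.38, -0.42 and 0.50 on the RASV12 arrays. Macrophage markers were lower in 5 of 13 (0 higher and 5 lower adjusted over the list alone, 0 and 0 with averaged pairs). The macrophage list had camera adjusted p = 0.0346, fry adjusted p = 0.0891, and adjusted p = 0.601 with an estimated correlation. It did not pass without RASV12 replicate 2 (adjusted p = 0.102), without shp53-first replicate 1 or 2 (adjusted p = 0.0772 and 0.0617), with normexp (adjusted p = 0.85), with its version after replaced backgrounds (adjusted p = 0.454) or among genes above background on all arrays (adjusted p = 0.569, range over its alternatives 1.68e-04 to 0.85).

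Ppbp (at least 437-fold), Rpl39l (at least 250.4-fold), Pf4 (at least 84.6-fold), Ccl6 (at least 66.7-fold) and Il1a (at least 35.6-fold) were lowest in shp53-first cells. The vesicular glutamate transporter gene Slc17a6 was at least 86.5-fold higher and Ddx3y at least 46.5-fold higher, and Ccl5 and Slfn8 changed by 6.38 ± 1.19 and 5.62 ± 1.03, Slfn8 being well above background on 1 RASV12 array. In all, 3664 of 14444 genes passed an adjusted p of 0.05 in limma, 1480 higher and 2184 lower, and 1908 of them differed at least 2-fold. With the closest pair of arrays in each group averaged, an alternative chosen after seeing the data, 393 genes passed, and the count was 194 with normexp background correction and 2706 when 77 extreme local backgrounds were first replaced. Leaving out RASV12 replicate 1 or 3 gave 2152 and 2142 genes, and leaving out shp53-first replicate 2 gave 2386.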

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

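Groups of 3 arrays are too small for the test for single outlying values, so nothing was singled out by it, and the 3 patterns weighed here were noticed in the data. The test of X-linked escape genes was set before its result was seen, and every other test in this part was chosen only after the result was seen.

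Xist was well above background on the 6 arrays with 1 vector and on none with 2 vectors, and the Y-linked genes Eif2s3y and Ddx3y the reverse. All 12 arrays had exactly 1 of these signals, which argues against loss of a sex chromosome within 1 line of cells, and 0 arrays differed from the rest of their group, which argues against single mislabelled arrays. If the cultures with 1 and 2 vectors differed in chromosomal sex, X-linked genes that escape inactivation would be higher with 1 vector, but only 1 of 4 separated the arrays, Ddx3x at 3.38 ± 0.24 against 2.64 ± 0.29 (log2 mean and SD, n = 6 each). Kdm5c read 1.87 ± 0.39 against 1.21 ± 0.14, Kdm6a -2.41 ± 0.38 against -2.54 ± 0.45 and Eif2s3x -0.24 ± 0.38 against 0.34 ± 0.12, so this prediction failed. The rule asked for every array with 1 vector to lie above every array with 2, which a small shift need not give. The vectors also differ along with the sex signals and may move these genes too, so this test cannot decide the question. The Xist and Y-linked signals argue against the same cells in both kinds of culture. Eif2s3y read -8.09 and -7.84 in shp53 and RASV12 cells, and 0.58 and 1.11 in shp53-first and RASV12-first cells. Xist read -0.78 and -1.01 in the former and -7.92 and -8.02 in the latter. How the cultures came to differ stays open, and every comparison of 1 vector with 2 carries this difference.

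In each group 1 pair of arrays lay far closer than the third array, and the nearer other pair was 2.7 to 3.51 times as far apart. Arrays of 1 slide deviated alike from their group means, with r over 0.1 on all 3 slides, in 1 of the 6 pairs of groups, and r ran from -0.34 to 0.26 between groups with 1 and 2 vectors, which argues against a slide effect alike in all 4 groups. The 1 pair was the 2 orders, with r of 0.60, 0.45 and 0.32, so that something shared by slide or by culture, which coincide, stays open there. Whether 1 RNA or culture was measured on 2 arrays cannot be told apart from closely matched cultures. The SD of the difference, relative to that of replicate spots, was 1.16 to 1.65 in the closest pairs and 3.62 to 5.97 in other pairs. No known duplicates on different slides were measured, so what either explanation would give is not known. No biological explanation was tested.

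Hox genes differed between the 2 orders of the vectors, 24 of 33. This share of 72.7% lay above that of 10000 random lists matched on signal, whose median was 6 genes and 95% range 2 to 10. The list was picked for this count, and its genes may move together, unlike those of random lists. The range therefore cannot serve as a test of chance. Without the arrays that stand apart 29 of 33 were called, so calls of Hox genes did not need those arrays. Random lists of that fit had a median of 16 and 95% range of 11 to 22, a range with the same limits. That fit keeps only the closest pairs, which may each be 1 RNA or culture, so a difference between single cultures stays open. Outgrowth of different parts of a mixed starting population may be a candidate explanation and cannot be told apart from a change within cells. In its test the cells with 1 vector stood for the starting population. Of the 6 genes shown to be over 16-fold apart, with bounds for signals at background, 66.7% had their higher mean within 4-fold of those cells or below them. This share lay between the bounds set for it. The sex-linked signals argue against the same cells in cultures with 1 and 2 vectors, so the share cannot decide the question.

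Macrophage markers differed within the shp53 group, where 13 markers read 4.05 log2 units higher on replicates 1 and 3 than on replicate 2 (median, range 3.29 to 5.28, SD 0.53).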

How the results depend on the processing

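The alternatives that averaged close arrays, left out arrays that stand apart together, left out X and Y genes, replaced extreme backgrounds or combined the replicate block with a fit of the 2 orders were chosen only after the result was seen. Counts are given for the 2 orders, RASV12 against shp53, shp53-first against shp53, RASV12-first against RASV12, RASV12-first against shp53, shp53-first against RASV12 and the genes with a shared direction, in this sequence. They were 2282, 3916, 5431, 5610, 6577, 3664 and 463. Within 1.5 times of these were all counts with quantile scaling, median centring, other filters, other gene summaries, a trended and robust spread, the authors' values and X and Y genes left out. Normexp as planned gave 65, 434, 383, 821, 349, 194 and 3. Its fitted background SD ran from 0.538 to 2496, and from 0.538 to 5.62 once 77 extreme local backgrounds on 8 arrays were replaced. With them replaced the counts that moved were 1284 for the 2 orders and 224 for the shared direction. Fits of 2 groups gave 1381 for the 2 orders and 306 for the shared direction, where the cause was not tested, and that of the 2 orders gave 2498 with the replicate block. In the other 5 comparisons they gave 4810, 4879, 4789, 5858 and 3123. A 2-fold limit gave 1297, 2262, 3009, 2950, 3612, 1908 and 249, and an adjusted p under 0.01 gave 1132, 2267, 3181, 3354, 4318, 1646 and 185, both stricter by construction. Averaging the closest arrays, with fewer replicates, gave 424, 1031, 1702, 1489, 2481, 393 and 43. Without the arrays that stand apart the counts were 6937, 8451, 9873, 9649, 10437, 8400 and 2480, with only the closest pairs left.

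Leaving out 1 array in turn gave 1485 to 2804, 2723 to 3854, 3803 to 5748, 4154 to 6285, 4973 to 7390, 2142 to 3780 and 297 to 643. With the replicate number as a block, which pairs arrays by slide, the counts were 2267, 3933, 5551, 5708, 6671, 3743 and 445. Deviations from the group mean had r across genes of 0.60, 0.45 and 0.32 between arrays of 1 number in the 2 orders.

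Nras in RASV12 against shp53 changed sign with normexp (0.0825), median centring (0.0565), the mean of its probes (0.63, adjusted p = 0.0243), without RASV12 replicate 1 (0.0273; range without 1 array -0.0805 to 0.0273) and without the arrays that stand apart (0.0129). Trp53 between the 2 orders read 0.57 with normexp, and neither gene passed before an alternative was applied. Trp53 passed without the arrays that stand apart (adjusted p = 0.0139, range over its alternatives 0.0139 to 0.751). Macrophage markers in RASV12-first against RASV12 cells changed sign with normexp, at 0.52. The cause of these turns was not tested. Of 184 named gene results, 74 lost their call with normexp, 2 with replaced backgrounds, 27 with averaged arrays and 5 in fits of 2 groups. Of 53 list calls, 52 were lost with an estimated correlation, 13 with fry and 8 without the arrays that stand apart. Genes near the background are limited by signal, and folds against them are bounds.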

Other observations

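The split counts in this part were set before their results were seen, and the lists were fixed in advance, while averaged pairs, replaced backgrounds and leaving out the arrays that stand apart were chosen only after the result was seen. Besides the Hox genes, 10 lists were called by camera in none of the 6 comparisons. Matrix proteases and their inhibitors, which remodel connective tissue, had 4 higher and 1 lower of 22 between the 2 orders (4 and 1 adjusted over the list alone, 1 and 0 with averaged pairs) and 8 higher and 6 lower in RASV12 against shp53 cells (8 and 6 adjusted over the list alone, 6 and 3 with averaged pairs), with fry adjusted p = 0.805 and 0.0691 in these 2 comparisons and a smallest camera adjusted p = 0.11 over the 6. Neural and glial markers had 2 higher and 5 lower of 11 between the 2 orders (2 and 5 adjusted over the list alone, 0 and 3 with averaged pairs) and 5 higher and 2 lower in RASV12 against shp53 cells (5 and 2 adjusted over the list alone, 4 and 2 with averaged pairs), with fry adjusted p = 0.0118 and 0.00442 in these 2 comparisons and a smallest camera adjusted p = 0.088 over the 6. Stem cell associated genes had 0 higher and 2 lower of 16 between the 2 orders (0 and 2 adjusted over the list alone, 0 and 1 with averaged pairs) and 6 higher and 1 lower in RASV12 against shp53 cells (6 and 1 adjusted over the list alone, 1 and 1 with averaged pairs), with fry adjusted p = 0.18 and 0.00237 in these 2 comparisons and a smallest camera adjusted p = 0.194 over the 6. Mesenchymal transition genes had 0 higher and 3 lower of 13 between the 2 orders (0 and 3 adjusted over the list alone, 0 and 1 with averaged pairs) and 3 higher and 5 lower in RASV12 against shp53 cells (3 and 5 adjusted over the list alone, 1 and 2 with averaged pairs), with fry adjusted p = 0.0434 and 0.258 in these 2 comparisons and a smallest camera adjusted p = 0.168 over the 6. CDK inhibitors, which restrain the cell cycle, had 0 higher and 1 lower of 7 between the 2 orders (0 and 1 adjusted over the list alone, 0 and 0 with averaged pairs) and 1 higher and 4 lower in RASV12 against shp53 cells (1 and 4 adjusted over the list alone, 1 and 2 with averaged pairs), with fry adjusted p = 0.431 and 0.00358 in these 2 comparisons and a smallest camera adjusted p = 0.0871 over the 6.

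Markers of other cell types were measured in small numbers. Endothelial markers had 1 higher and 1 lower of 6 between the 2 orders (2 and 1 adjusted over the list alone, 0 and 0 with averaged pairs) and 2 higher and 0 lower in RASV12 against shp53 cells (2 and 0 adjusted over the list alone, 2 and 0 with averaged pairs), with fry adjusted p = 0.654 and 0.00155 in these 2 comparisons and a smallest camera adjusted p = 0.125 over the 6. Epithelial markers had 0 higher and 1 lower of 6 between the 2 orders (0 and 1 adjusted over the list alone, 0 and 0 with averaged pairs) and 2 higher and 0 lower in RASV12 against shp53 cells (2 and 0 adjusted over the list alone, 0 and 0 with averaged pairs), with fry adjusted p = 0.092 and 0.305 in these 2 comparisons and a smallest camera adjusted p = 0.119 over the 6. Skeletal muscle markers had 1 higher and 1 lower of 5 between the 2 orders (2 and 1 adjusted over the list alone, 0 and 1 with averaged pairs) and 1 higher and 1 lower in RASV12 against shp53 cells (1 and 2 adjusted over the list alone, 1 and 0 with averaged pairs), with fry adjusted p = 0.549 and 0.769 in these 2 comparisons and a smallest camera adjusted p = 0.43 over the 6. Adipocyte markers had 0 higher and 1 lower of 5 between the 2 orders (0 and 2 adjusted over the list alone, 0 and 0 with averaged pairs) and 0 higher and 3 lower in RASV12 against shp53 cells (1 and 3 adjusted over the list alone, 0 and 0 with averaged pairs), with fry adjusted p = 0.18 and 0.046 in these 2 comparisons and a smallest camera adjusted p = 0.0806 over the 6. Cartilage and bone markers had 1 higher and 2 lower of 7 between the 2 orders (1 and 2 adjusted over the list alone, 0 and 0 with averaged pairs) and 1 higher and 1 lower in RASV12 against shp53 cells (1 and 1 adjusted over the list alone, 0 and 1 with averaged pairs), with fry adjusted p = 0.567 and 0.775 in these 2 comparisons and a smallest camera adjusted p = 0.529 over the 6. The sex genes of the X and Y chromosomes were called as a list in the 4 comparisons of 2 vectors with 1, with camera adjusted p = 0.0173, 0.0128, 0.0295 and 0.00381, and adjusted p = 0.563, 0.629, 0.635 and 0.459 with an estimated correlation (fry adjusted p = 1.13e-07, 8.38e-08, 6.81e-08 and 1.41e-07). In each, 3 of 4 were higher and 1 lower (3 and 1 adjusted over the list alone, 3 and 1 with averaged pairs). In RASV12-first against shp53 cells the list was not called without RASV12-first replicate 1 (adjusted p = 0.0571), with normexp (adjusted p = 0.0716), with replaced backgrounds (adjusted p = 0.093), with median centring (adjusted p = 0.109), in a fit of 2 groups (adjusted p = 0.0536) or without the arrays that stand apart (adjusted p = 0.269, range over its alternatives 6.81e-08 to 0.635). In shp53-first against shp53 cells it was not called with normexp, with replaced backgrounds or without the arrays that stand apart (adjusted p = 0.296, 0.0958 and 0.235, range over its alternatives 1.13e-07 to 0.563). In RASV12-first against RASV12 cells it was not called with replaced backgrounds or without the arrays that stand apart (adjusted p = 0.0546 and 0.139, range over its alternatives 8.38e-08 to 0.629), and in shp53-first against RASV12 cells without the arrays that stand apart (adjusted p = 0.12, range over its alternatives 1.41e-07 to 0.459).

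The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and for each comparison 1 of the 10 splits, the real one, gave as many genes as were called. The real and the highest other counts were 2282 and 0 for the 2 orders, and 3916 and 32 for RASV12 against shp53. They were 5431 and 18 for shp53-first against shp53. For the other 3 comparisons they were 5610 and 0, 6577 and 0, 3664 and 0.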
